A study of Mus musculus with 4 samples.

How the data were processed

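Whole-liver RNA of 4 samples, 2 per genotype, was hybridised to 1 Illumina array each; the labels do not say whether the samples came from separate animals. Per the labels' protocols, RNA was extracted with Trizol, cleaned on RNeasy columns with DNase treatment, and made into biotinylated cRNA with an Ambion MessageAmp kit. The authors deposited a table of linear probe intensity values for each array, named by sample, which was used here. The deposited intensities are already normalized between arrays (medians of 81.5 to 81.9 units and 95th percentiles of 1704 to 1714), are never negative, and carry no detection p; the normalization method is not given in the sources used here, and no background appears to have been subtracted. A second table, of values before normalization, has 4 columns whose names match no sample label, and these 4 columns were not used. Groups and replicate numbers come from the sample titles.

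From the deposited intensities, background was corrected on each array with limma's normexp method and an offset of 50, and values were put on the log2 scale. Fold changes are on this scale, so they understate the change of dim genes. Where a gene lay below 100 units on both arrays of 1 group only, the text gives a lower bound ("at least N-fold"): the mean log2 value of the brighter group against that of the dimmer, with values under 100 units raised to the lowest value read above 100 units on that array. The floor of 100 units was chosen after the values were seen. No fold is given where both groups lay below it.

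Probes were named through the platform's annotation, with symbols updated by gene identifier to the GRCm38.p6 RefSeq table; all but 11 identifiers matched. Of 25697 probes 23978 had 1 gene, 0 had several, and 1719 were unnamed here and were tested apart. Each of the 16593 genes was represented by its probe with the highest mean, and 4777 genes had more than 1 probe. Of the named genes 48 had several probes and 26 of these had another probe above 100 units on average. That other probe passed in the opposite direction in 0 genes and did not pass in 4, which were Asns, Gusb, Mlkl and Tk1. No genome was used, so no positions are given. Probes of the near-identical Mup, Cyp2c, Cyp3a, Cyp4a, Saa, Orm, Gsta, Gstm, Lyz and H2 families are open to cross-hybridisation.

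The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 2 residual degrees of freedom, prior degrees of freedom 6.84, prior SD 0.101), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Every adjusted p given for a gene is limma's. Gene lists were compared with the other genes by camera in limma, with a preset correlation of 0.01 and adjustment over 29 lists, and again with the correlation estimated from the data and with fry, which tests whether a list's genes move on balance 1 way. With an estimated correlation camera rests on the 2 residual degrees of freedom, so it had very little power here. A list that missed the threshold that way is not evidence against its shift. The lists hold 732 entries, 648 of them measured. An exact permutation test of 2 against 2 arrays cannot give a p below 0.333, so none was used. The labels name no batch, slide or scan, so batches could not be examined. Differences between list medians carry 95% intervals from 10000 bootstrap draws over genes, and the clock genes' change and SD within groups were set against 10000 random lists matched on mean expression; genes are not independent replicates, so these intervals describe the lists.

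The groups, the test, the 29 lists, the alternatives and the rule for named genes were fixed before the data were examined. That rule takes Map3k7, the 10 largest rises and 10 largest falls among genes that passed with the groups apart, and in each list up to 4 passed members with the largest change plus up to 2 that went against most. The text does not give every gene that the rule took, and genes given beside or in place of these were chosen after their values were seen. Counts of named genes cover all those the rule took. The plan departed from its text in 3 points: the normalized table replaced the one before normalization; no quantile step was added to values already normalized, which was run as an alternative; and no filter on detection p could be applied.

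The procedure was tested on simulated data: 20 sets of 2 against 2 arrays with the means of the 16593 genes, 200 of which were changed. Each gene's variance was drawn from limma's fitted prior, and noise was independent between genes. The simulated data thus follow the model that the test assumes. Of genes changed by 0.5 on the log2 scale 38.9% were called, of those changed by 1 98.7%, and of those changed by 2 100%, and 5.17% of calls were false. Camera called a list of 30 genes shifted by 0.3 in 20 of 20 sets and an unchanged list in 0 of 20. Alternatives covered the background correction, normalization, probe choice, variance prior, array weights, a replicate block, each array left out, the threshold and the set test, and 3 more were chosen after the data were seen: an offset of 16, quantile normalization after normexp, and a filter at 100 units on at least 2 arrays.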

Results

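RNA from whole liver was measured on Illumina expression arrays in mice 4 weeks old, in 2 samples with a floxed TAK1 gene and no Cre (WT) and 2 with the same floxed gene and Cre driven by the albumin promoter (TAK1 KO), which deletes TAK1 in hepatocytes. TAK1, encoded by Map3k7, is a kinase that passes signals from cytokine and Toll-like receptors to NF-kB, JNK and p38. The comparison asks how liver gene expression differs when hepatocytes lack TAK1, and because the WT genotype carries no Cre, Cre and the deletion differ together. The mice were untreated and of the C57BL/6 strain. Each array held 25697 probes with a median deposited intensity between 81.5 and 81.9 units, and 40.6% to 40.9% of probes lay above 100 units. Across genes, log2 values correlated at 0.995 between the WT arrays, 0.994 between the TAK1 KO arrays and 0.970 to 0.974 between the groups, although genes are not independent replicates. With 2 arrays in each group, their number limits the precision of every value. SEs and p-values rest only on the spread between these samples, pooled for each gene with limma's prior over all genes. Because the labels do not say whether the 4 samples came from separate animals, that spread may be technical. In 19 clock genes the mean SD within groups was 0.44, against a median of 0.11 in random lists matched on expression. This argues against purely technical spread in at least 1 group, since the SD pools both groups. The check was chosen after the results were seen.

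Xist, the RNA that coats the inactive X chromosome of female cells, read between 575 and 853.4 units over the 4 arrays on its brighter probe and between 313.8 and 503.5 units on its other probe. The Y-linked genes Eif2s3y and Kdm5d read 53.3 to 69.3 and 54.5 to 59.7 units, and Uty 112.4 to 142.2 units. The labels give all 4 samples as male. Xist did not pass the test between the groups (adjusted p = 0.253), and neither did Eif2s3y (0.110), Kdm5d (0.713) or Uty (0.517).

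Map3k7 itself read 155 and 138.4 units in WT and 125.3 and 117.9 units in TAK1 KO liver on its 1 probe, a log2 difference of -0.26 ± 0.10 (SE, n = 2 per group) that did not pass (adjusted p = 0.116). Which part of the transcript the probe reads is not known here, so it does not check the genotype labels, and whole liver also holds cells in which the albumin promoter is not active.

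The largest rises in TAK1 KO liver were in Ly6d, Igf2, Gpnmb, Mmp12 and Gsta1, and the largest falls in Cyp2b13, Sult2a8, Depp1, Rgs16 and Mup6. Ly6d, a surface protein seen in liver tumours of mice, was at least 46.0-fold higher in TAK1 KO (adjusted p = 2.08e-07), and the fetal growth factor Igf2 was 40.0-fold higher (log2 5.32 ± 0.16 SE, adjusted p = 4.74e-07). Gpnmb, a glycoprotein of phagocytes, was at least 21.9-fold higher and Mmp12, the macrophage elastase, at least 14.6-fold higher. The glutathione transferases Gsta1 and Gsta2 rose by log2 3.99 ± 0.17 and 3.32 ± 0.20 (SE), the protease inhibitor Slpi 13.8-fold, the tetraspanin Cd63 11.6-fold, D17H6S56E-5 11.0-fold and the galectin Lgals3 10.4-fold. Among the falls, the female-biased cytochrome P450 gene Cyp2b13 was 40.0-fold lower (log2 -5.32 ± 0.18 SE, adjusted p = 7.99e-07) and the sulfotransferase Sult2a8 19.6-fold lower. Depp1 fell by 4.00 ± 0.28 (SE) on the log2 scale. The signalling regulator Rgs16 was lower at least 12.9-fold, the urinary proteins Mup6 and Mup2 11.7-fold and 6.74-fold, the carboxylesterase Ces3b 6.22-fold, Chac1 at least 4.42-fold, the glycosyltransferase Ugt3a1 5.78-fold and the lipogenic regulator Thrsp 5.70-fold. Thrsp missed the threshold without WT replicate 2 (adjusted p = 0.0653), and with a robust prior that follows intensity Thrsp (0.272) and Slpi (0.0525) both missed it.

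In all, 3022 of 16593 genes passed an adjusted p of 0.05 in limma's moderated test, of which 1744 rose and 1278 fell in TAK1 KO, and 526 of them changed by at least 1 on the log2 scale (319 up, 207 down). Among the 7794 genes above 100 units on at least 2 arrays, 2898 passed, 1651 upward and 1247 downward. The counts given below for lists and families of expressed genes are to be read against these. In each of the 3022 genes both TAK1 KO arrays lay on the same side of both WT arrays; 53.9% of all genes did so, where chance gives 33.3%. Leaving out 1 WT array lowered the count, to 1823 without WT replicate 1 and 1800 without WT replicate 2. Of the 29 gene lists fixed in advance, 10 passed upward and 9 downward with camera's preset correlation, and 0 of these passed with the correlation estimated from the 4 arrays (11 lists passed with fry). The estimated correlation leaves camera 2 residual degrees of freedom, too few for a miss to count against a list.

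**Figure D1:**
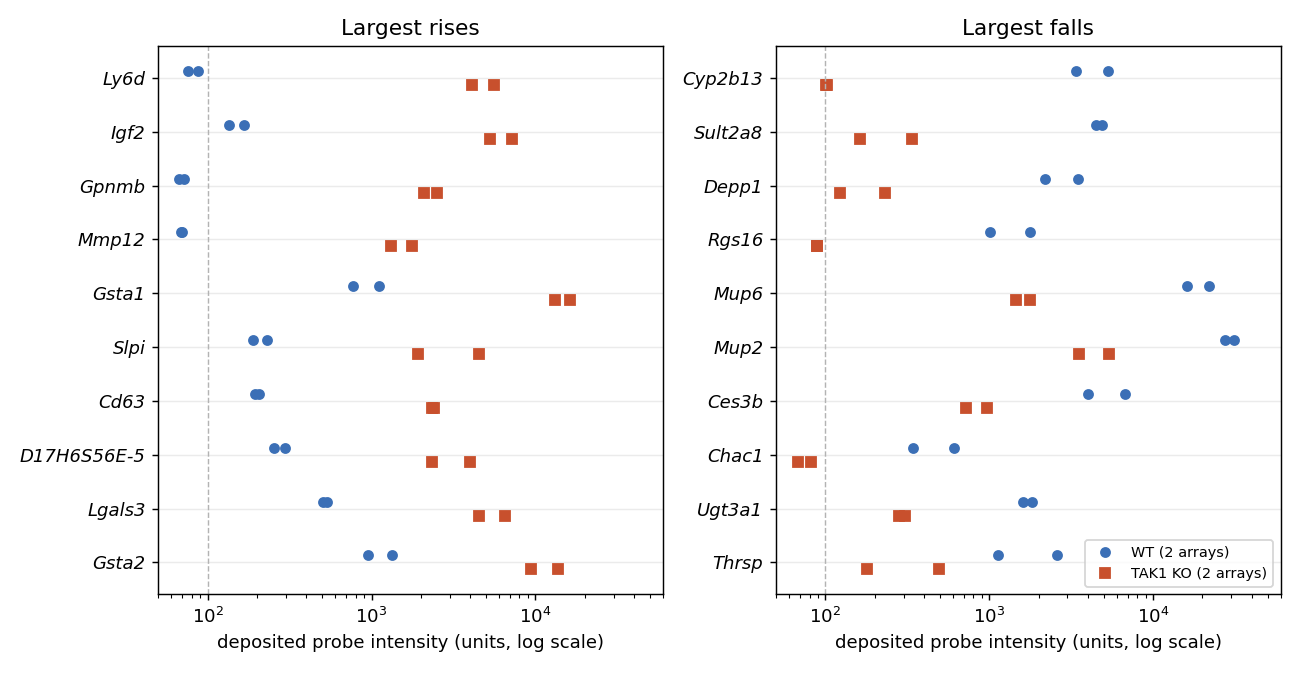
Deposited probe intensity (units, log scale) of the 10 genes with the largest rise (left) and the 10 with the largest fall (right), with 1 point per array, circles for WT and squares for TAK1 KO, and a dashed line at 100 units. In each gene both TAK1 KO points lie beyond both WT points, and Ly6d lies below 100 units in WT and at 4122.2 or more in TAK1 KO.

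Among genes of the extracellular matrix and of stellate cells, the liver's collagen-producing cells, most were higher in TAK1 KO liver. Of 34 measured members 27 rose and 0 fell (29 and 0 adjusted over the list alone), and the list's median log2 fold change was 1.20 (1.18 with values below 100 units set to 100). The collagenase Mmp13 was at least 6.16-fold higher, the proteoglycan Lum rose 4.68-fold, Lgals1 4.61-fold and the collagen cross-linker Loxl1 4.44-fold. Acta2, the smooth muscle actin of activated stellate cells, rose 4.15-fold, the collagen Col3a1 rose 3.08-fold, and Col1a1 was at least 3.07-fold higher. The list passed camera with an adjusted p of 2.23e-23, and with adjusted p = 0.332 with an estimated correlation.

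Markers of macrophages and monocytes moved the same way, with 18 of 27 up and 0 down (19 and 0 adjusted over the list alone; median log2 0.74, the same with the floor). Trem2, a receptor for lipids on macrophages, was at least 2.35-fold higher, the lysozymes Lyz1 and Lyz2 rose 3.43-fold and 3.10-fold, and Adgre1, which encodes F4/80, rose 1.92-fold. The list's adjusted p was 5.16e-14 (adjusted p = 0.288 with an estimated correlation). Genes of lymphocytes and antigen presentation rose in 7 of 26 cases and fell in 0 (8 and 0 adjusted over the list alone; adjusted p = 0.00563, and adjusted p = 0.354 with an estimated correlation), with a median log2 of 0.09, or -0.00093 with the floor. Of those 7, the class II genes H2-Aa, H2-Ab1 and H2-Eb1 rose 2.06-fold, 1.91-fold and 1.86-fold, and Cd74 1.73-fold. Among neutrophil markers 5 of 14 rose and 0 fell (5 and 0 adjusted over the list alone), with a median log2 of 0.10, or 0.0042 with the floor, led by S100a8 at 3.92-fold and S100a9 at 2.15-fold (list adjusted p = 0.0206, and adjusted p = 0.354 with an estimated correlation). For the neutrophil list the call was lost among probes above 100 units (adjusted p = 0.0508), and its rises numbered 3 without WT replicate 2. Without TAK1 KO replicate 2, 1 macrophage marker fell.

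Bile duct and progenitor markers rose in 7 of 17 cases and fell in 0 (8 and 0 adjusted over the list alone; adjusted p = 5.89e-06, and adjusted p = 0.288 with an estimated correlation), and their median log2 of 0.26 became -0.00093 with values below 100 units set to 100. The 4 largest rises were in Tnfrsf12a, the receptor for the cytokine TWEAK (7.36-fold), in Krt8 and Krt18 (5.39-fold and 4.83-fold), which hepatocytes also express, and in Krt23 (2.30-fold). The bile duct keratins Krt7 and Krt19 did not pass (adjusted p = 0.199 and 0.181). Of the sinusoidal endothelial markers 4 of 20 fell and 0 rose (5 and 1 adjusted over the list alone), with Lyve1 1.60-fold lower (adjusted p = 0.00165), and the list did not pass (adjusted p = 0.447; median 0.01, mean -0.06, test downward). The other 3 calls were not stable: Ehd3 missed the threshold without WT replicate 2 (adjusted p = 0.0849), and Mrc1 and Oit3 missed it without WT replicate 1 (0.246 and 0.132) and WT replicate 2 (0.0969 and 0.150). The endothelial falls numbered 2 without WT replicate 1 and 1 without WT replicate 2, and 1 marker rose without WT replicate 2 or TAK1 KO replicate 1.

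**Figure D2:**
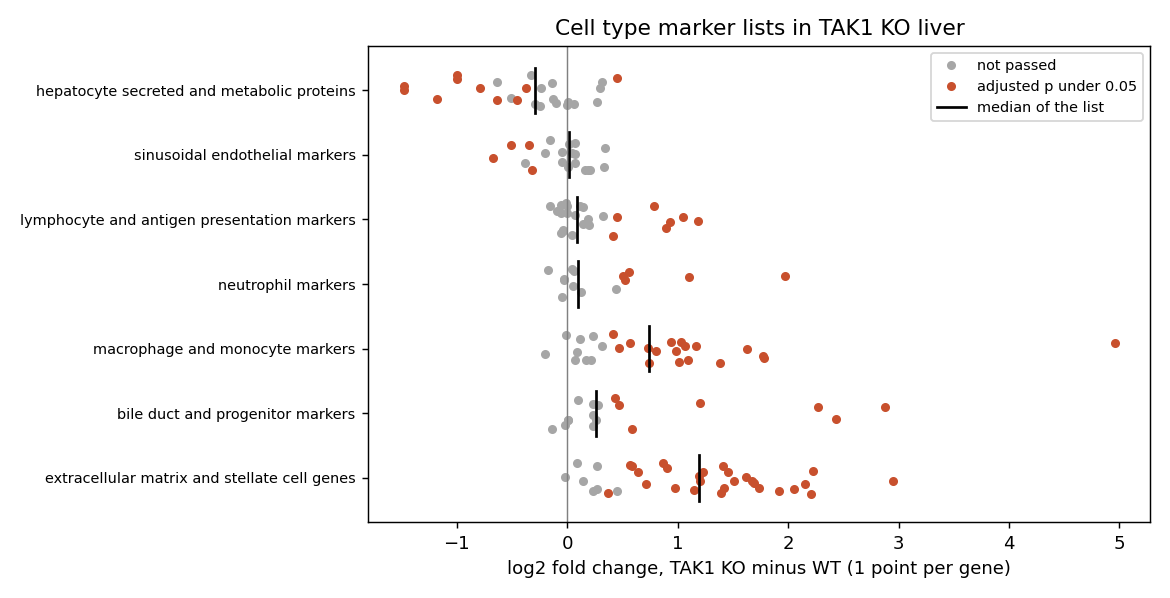
Log2 fold change (TAK1 KO minus WT) of each measured member of 7 marker lists, 1 point per gene, coloured where the adjusted p was under 0.05, with the list's median as a black line. Medians lie at 1.20 for extracellular matrix and stellate cell genes, 0.74 for macrophage markers, 0.01 for endothelial markers and -0.29 for hepatocyte proteins.

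Of 32 genes of cell division 21 rose in TAK1 KO liver and 1 fell (22 and 1 adjusted over the list alone), with a median log2 fold change of 0.86, or 0.74 with values below 100 units set to 100. Cyclin D1 (Ccnd1) rose 3.52-fold, the spindle protein Prc1 3.31-fold, the mitotic kinase Plk1 3.21-fold and Nusap1 2.67-fold. Tk1, thymidine kinase, was 1.36-fold lower, a call lost without WT replicate 2 (adjusted p = 0.102). With the robust prior Plk1 missed the threshold (adjusted p = 0.0619). Macrophage markers (18 of 27) and matrix and stellate genes (27 of 34) rose in the same whole-liver samples. Camera gave the list an adjusted p of 8.82e-12 (adjusted p = 0.349 with an estimated correlation).

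The list of fetal liver and liver tumour genes had 16 of 24 members up and 0 down (18 and 0 adjusted over the list alone). Besides Ly6d, Igf2 and Lgals3, alpha-fetoprotein (Afp) rose 8.07-fold (log2 3.01 ± 0.12 SE, adjusted p = 1.91e-06), the Golgi protein Golm1 5.05-fold, Akr1c18 at least 4.33-fold and Tff3 at least 4.83-fold. Its median log2 fold change was 0.70 (0.69 with the floor) and its adjusted p 5.16e-14 (adjusted p = 0.288 with an estimated correlation). Targets of NRF2, the regulator of antioxidant genes, rose in 14 of 25 cases and fell in 2 (16 and 2 adjusted over the list alone; adjusted p = 4.69e-06, and adjusted p = 0.354 with an estimated correlation). Gstm3 rose 5.44-fold, Cbr3 2.89-fold, Gstp1 2.75-fold and Nqo1 1.74-fold, while catalase (Cat) fell 1.83-fold. Macrophage, stellate and cell division genes rose in the same livers. The NRF2 rises numbered 9 without WT replicate 2, and the falls 1 there and 4 without TAK1 KO replicate 2. The Gsta and Gstm genes belong to near-identical families, whose probes are open to cross-hybridisation.

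Of the enzymes that metabolise drugs 18 of 27 were lower in TAK1 KO liver and 1 was higher (19 and 2 adjusted over the list alone), with a median log2 fold change of -0.72 (-0.66 with the floor). Ugt3a2 was 4.19-fold lower, Cyp2a5 3.66-fold, Cyp2e1 2.42-fold and Cyp2c29 2.23-fold, and Nr1i3, the nuclear receptor CAR that regulates many such genes, 1.79-fold. The list passed downward with an adjusted p of 5.86e-10 (adjusted p = 0.340 with an estimated correlation). For bile acid synthesis and transport 14 of 22 genes fell and 2 rose (15 and 2 adjusted over the list alone; adjusted p = 3.17e-08, and adjusted p = 0.354 with an estimated correlation). The cholesterol exporter subunits Abcg8 and Abcg5 fell 3.46-fold and 2.45-fold, Cyp7b1 3.41-fold, the bile acid ligase Slc27a5 2.88-fold and the uptake transporter Slco1b2 2.86-fold. The transporters Slc51b and Abcb4, which move bile acids out of the cell and phospholipid into bile, rose 2.26-fold and 1.65-fold. In the same livers the medians of macrophage and of matrix and stellate genes were 0.74 and 1.20, and that of general hepatocyte proteins -0.29. The 1 risen drug-metabolising gene became 0 without WT replicate 1 and 2 without WT replicate 2 or TAK1 KO replicate 2.

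Hepatocyte secreted and metabolic proteins fell in 9 of 25 cases and rose in 1 (13 and 4 adjusted over the list alone), with a median log2 fold change of -0.29. Histidine ammonia lyase (Hal) and tryptophan dioxygenase (Tdo2) were both 2.79-fold lower, the urea cycle enzyme Otc 2.26-fold and glucose-6-phosphatase (G6pc) 1.99-fold, whereas Apoa2 was 1.37-fold higher, a call lost without WT replicate 1 (adjusted p = 0.0695) and with quantile normalization (0.216). Without TAK1 KO replicate 2, 2 of these proteins rose. The list's adjusted p was 0.000196 (adjusted p = 0.354 with an estimated correlation). Markers of macrophages and of stellate cells rose in the same livers, at medians of 0.74 and 1.20.

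In de novo lipogenesis, the synthesis of fatty acids, 9 of 17 genes fell in TAK1 KO liver and 1 rose (11 and 1 adjusted over the list alone; median log2 -0.53; adjusted p = 6.95e-06, and adjusted p = 0.354 with an estimated correlation). After Thrsp, the glucose-sensing factor ChREBP (Mlxipl) fell 2.48-fold, acetyl-CoA synthetase (Acss2) 2.24-fold, pyruvate kinase (Pklr) 2.08-fold and Srebf1 1.75-fold. In cholesterol synthesis 7 of 18 were down and 0 up (10 and 1 adjusted over the list alone; adjusted p = 2.30e-05, and adjusted p = 0.382 with an estimated correlation). Tm7sf2 fell 2.13-fold, Msmo1 2.01-fold, Sc5d 1.97-fold and Stard4 1.94-fold. Macrophage markers (18 of 27) and matrix and stellate genes (27 of 34) rose in the same livers, and hepatocyte proteins had a median of -0.29. The lipogenic falls numbered 4 without WT replicate 2 and the rises 0 without WT replicate 1, and the falls in cholesterol synthesis 4 without either WT array and 11 without TAK1 KO replicate 2, with 1 rise without TAK1 KO replicate 1.

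Fatty acid oxidation and PPARa target genes were lower in 11 of 32 cases and higher in 3 (11 and 3 adjusted over the list alone). The phosphatidate phosphatase Lpin1 fell 2.38-fold, Etfdh 1.94-fold, the omega-hydroxylase Cyp4a14 1.73-fold and the peroxisomal enzyme Ehhadh 1.56-fold. Pdk4 and the lipid droplet protein Plin2 were 1.68-fold and 1.42-fold higher, calls that were lost without WT replicate 1 (adjusted p = 0.170 and 0.157) and without WT replicate 2 (0.0762 and 0.0771), for Plin2 also without TAK1 KO replicate 1 (0.0552). The falls numbered 6 without WT replicate 1 and 7 without WT replicate 2, and the rises 0 without either and 1 without TAK1 KO replicate 1. Macrophage and matrix genes rose in these livers too (medians 0.74 and 1.20). The list passed downward with an adjusted p of 0.000541 (adjusted p = 0.354 with an estimated correlation).

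Autophagy genes fell in 7 of 27 cases and rose in 0 (7 and 1 adjusted over the list alone; adjusted p = 0.00209, and adjusted p = 0.365 with an estimated correlation). The conjugating enzyme Atg3 was 2.48-fold lower (log2 -1.31 ± 0.10 SE, adjusted p = 5.72e-05), the autophagosome protein Gabarapl1 2.16-fold, the initiating kinase Ulk1 1.64-fold and Atg10 1.62-fold. Lysosomal genes moved upward, with 10 of 26 up and 1 down (11 and 3 adjusted over the list alone; adjusted p = 0.00812, and adjusted p = 0.354 with an estimated correlation). Besides Cd63, the glucuronidase Gusb rose 1.87-fold and cathepsin S (Ctss), a protease of macrophages, 1.78-fold, and macrophage markers rose in the same livers (median log2 0.74). Cathepsin L (Ctsl) was 1.83-fold lower, a call lost without WT replicate 1 (adjusted p = 0.0779) and with the robust prior (0.0540). For the lysosomal list the call was lost among probes above 100 units (adjusted p = 0.0671). Its rises numbered 6 without WT replicate 1 and 5 without WT replicate 2, and the autophagy falls 4 without WT replicate 1, with 1 rise without TAK1 KO replicate 1.

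Inflammatory genes split in direction. Of the NF-kB targets, cytokines and chemokines 11 of 29 rose and 4 fell (12 and 4 adjusted over the list alone). The chemokine Ccl4 was at least 3.84-fold higher, the adhesion molecules Vcam1 and Icam1 rose 3.30-fold and 1.69-fold and Cxcl16 1.74-fold. The chemokine Cxcl9 fell 2.37-fold, a call lost with the robust prior (adjusted p = 0.260). The Cxcl9 call was also lost without WT replicate 1 (log2 -1.47) and without WT replicate 2 (log2 -1.02). The NF-kB inhibitor Nfkbia, itself an NF-kB target, fell 1.70-fold and Saa3 at least 1.70-fold. Macrophage markers rose in the same livers (18 of 27, median log2 0.74). The NF-kB list's median log2 was 0.24, or -0.00093 with values below 100 units set to 100. The list's adjusted p was 0.00383 (adjusted p = 0.354 with an estimated correlation), and 0.0568 without TAK1 KO replicate 2. Among probes above 100 units it was 0.151. The rises numbered 6 without WT replicate 1 and 5 without WT replicate 2, and the falls 2 without WT replicate 1.

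Of 25 acute phase genes 4 rose and 6 fell (4 and 7 adjusted over the list alone), and the list did not pass (adjusted p = 0.208). Lipocalin 2 (Lcn2) rose 5.98-fold, the antagonist Il1rn 2.17-fold and Socs3 2.10-fold, whereas Saa4 fell 2.73-fold, Lbp 1.96-fold and Crp 1.76-fold. Orm2 and Orm1 fell 2.24-fold and 2.17-fold. With the robust prior Lcn2, Orm2 and Orm1 missed the threshold (adjusted p = 0.0556, 0.1955 and 0.0924). The calls of Orm2 and Orm1 were also lost without WT replicate 1 (log2 -1.03 and -1.13) and without WT replicate 2 (-1.29 and -1.11). Among 28 interferon-induced genes 1 rose and 4 fell (1 and 3 adjusted over the list alone), with Gbp2 1.59-fold lower (a call lost with the mean of its probes, adjusted p = 0.105), and the list's adjusted p was 0.456, or 0.0305 without TAK1 KO replicate 2. Immediate-early genes, which respond within minutes to stimuli and handling, rose in 4 of 19 cases and fell in 1 (4 and 1 adjusted over the list alone; adjusted p = 0.305). Egr2 was at least 2.59-fold higher, Ier3 and Klf6 rose 2.34-fold and 2.15-fold, and Zfp36 fell 2.41-fold. The acute phase falls numbered 3 without either WT array. The interferon falls numbered 2 without either WT array and 7 without TAK1 KO replicate 2, and the rises 0 without WT replicate 1 and 2 without TAK1 KO replicate 1. Immediate-early falls numbered 2 without either WT array or TAK1 KO replicate 1.

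Of 32 genes whose liver expression differs between the sexes 14 fell in TAK1 KO liver and 3 rose. Among the female-biased genes 5 of 15 fell and 0 rose (6 and 0 adjusted over the list alone; adjusted p = 1.51e-05, and adjusted p = 0.288 with an estimated correlation). After Cyp2b13, Cyp2b9 fell 4.48-fold, Cyp4a31 2.86-fold and Hao2 2.48-fold. The list's median was -0.22, or -0.0064 with values below 100 units set to 100, because most of its other members were dim in both groups. For male-biased genes 9 of 17 fell and 3 rose (9 and 3 adjusted over the list alone; median log2 -0.74; adjusted p = 0.00511, and adjusted p = 0.365 with an estimated correlation). Serpina1e fell 4.36-fold, Hsd3b5 at least 2.06-fold, Nudt7 2.82-fold and Mup20 1.80-fold, and Spink1 and Cyp2d9 rose 6.08-fold and 2.72-fold. Serpina1e and Hsd3b5 missed the threshold with the robust prior (adjusted p = 0.0587 and 0.203). The labels give the samples as male, and Xist read at least 313.8 units on each array on both of its probes.

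Targets of p53 and cell death genes rose in 9 of 26 cases and fell in 3 (9 and 3 adjusted over the list alone). The cell cycle inhibitor Cdkn1a rose 3.26-fold, Plk3 2.68-fold, Phlda3 at least 1.95-fold and Mdm2 1.81-fold, while the death receptor Fas fell 1.65-fold. The list did not pass (adjusted p = 0.180), although it did without TAK1 KO replicate 1 (adjusted p = 0.0396). In the ER stress and amino acid list 5 of 23 rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p = 0.558), and its largest change was the fall of Chac1, a glutathione-degrading enzyme induced by ER stress, at least 4.42-fold (adjusted p = 9.85e-05). Herpud1 fell 1.40-fold, a call lost without WT replicate 1 (adjusted p = 0.179), WT replicate 2 (0.145) and TAK1 KO replicate 2 (0.132), and Atf3 and Psat1 were at least 1.36-fold and 1.55-fold higher. Members of the TAK1 pathway rose in 2 of 17 cases and fell in 2 (2 and 3 adjusted over the list alone; adjusted p = 0.878). Mapk8, which encodes JNK1, was 1.52-fold lower and Rela, the NF-kB subunit p65, 1.41-fold higher, both calls lost without WT replicate 2 (adjusted p = 0.0556 and 0.0542). Without WT replicate 1 the rises numbered 5 for p53 targets and 3 for ER stress genes. The ER stress falls numbered 1 without either WT array or TAK1 KO replicate 2. For the TAK1 pathway the falls numbered 1 without either WT array or TAK1 KO replicate 1, and the rises 0 without WT replicate 2.

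Markers of tissue next to the liver and of blood did not pass as lists. Of the pancreatic acinar genes 4 of 14 fell and 0 rose (4 and 0 adjusted over the list alone; median 0.01, mean -0.21, test downward), among them the amylase Amy2a5 2.11-fold and the elastase Cela1 1.72-fold; the list's adjusted p was 0.118, or 0.0241 without TAK1 KO replicate 2. Of 11 erythroid genes 2 rose and 2 fell (2 and 2 adjusted over the list alone; adjusted p = 0.558), with the haem enzyme Alas2 2.29-fold lower and the transferrin receptor Tfrc 2.38-fold higher. Of 11 adipocyte genes 1 rose and 2 fell (1 and 2 adjusted over the list alone; adjusted p = 0.251), with the carbonic anhydrase Car3, which hepatocytes also express, 3.95-fold lower. The erythroid rises numbered 1 without WT replicate 2. The adipocyte falls numbered 1 without either WT array or TAK1 KO replicate 2, and the rises 0 without either WT array and 2 without TAK1 KO replicate 2.

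**Figure D3:**
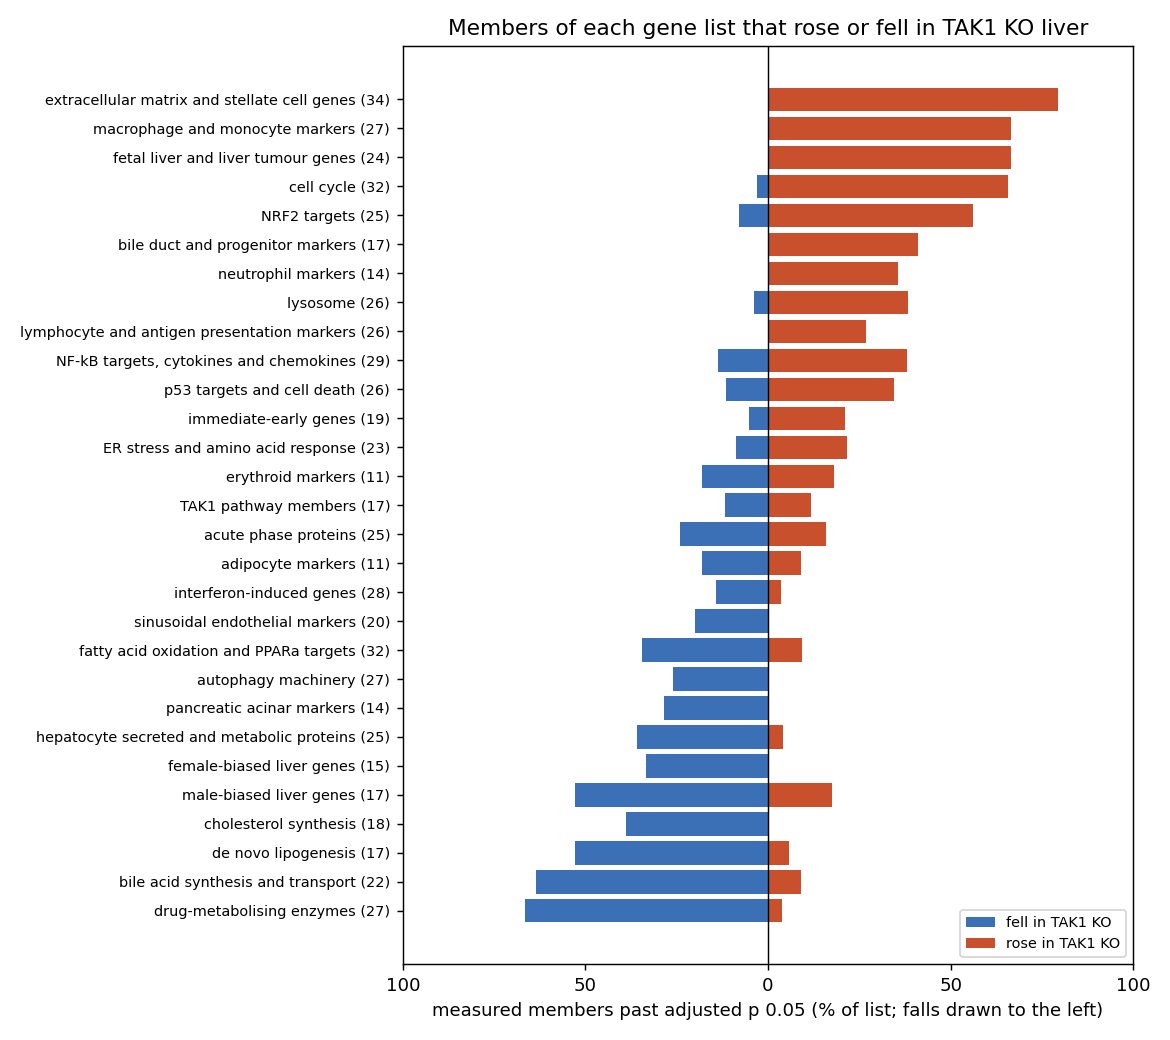
Share of each list's measured members (number in brackets) that rose (bars to the right) or fell (bars to the left) past an adjusted p of 0.05, in percent. Extracellular matrix and stellate cell genes stand at one end, with 27 of 34 risen, and drug-metabolising enzymes at the other, with 18 of 27 fallen.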

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

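The test of probes without a gene name was chosen after they were seen to carry signal. Of the 1719 probes with no gene name here, 237 passed limma's test (adjusted among these probes), 131 of them higher and 106 lower in TAK1 KO liver, and they drew attention because they lie outside the comparison of named genes. The share that passed was 13.8%, against 18.2% of named genes. The largest log2 changes were 5.49 ± 0.30 (SE) upward and -2.81 ± 0.13 downward, with adjusted p-values of 7.73e-06 and 4.15e-06. No explanation was tested for them.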

How the results depend on the processing

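The settings with an offset of 16, with quantile normalization after normexp and with the 100-unit filter were chosen after the results were seen. The 3022 passed genes became 2922 without background correction and with quantile normalization, 2995 with cyclic loess, 3006 with median centring, 2972 with the deposited values on the log2 scale, 2733 with the mean over a gene's probes, 2830 with the robust prior, 3038 with array weights, 2323 with an offset of 16, 2950 with quantile normalization after normexp and 2898 of 7794 genes above 100 units. At an adjusted p of 0.1 3748 passed, at an unadjusted p of 0.05 4641, and 526 passed with a log2 change of at least 1. Leaving out 1 array gave 1800 to 3311 passed genes, 1036 to 1877 risen and 755 to 1434 fallen; the lone array was assumed to vary like the other group. The 2 lower counts came without WT replicate 1 (1823) and WT replicate 2 (1800), and the cause was not tested. Of 141 named genes all but Map3k7 passed, because the rule took passed genes. Leaving out 1 array could not reverse the passed ones, because both TAK1 KO arrays lay beyond both WT arrays in each. Map3k7 reached an adjusted p of 0.05 under no setting, though its unadjusted p in limma was 0.0279. At an adjusted p of 0.05 with no minimum change, 102 of the other 140 passed under every setting that kept them (the filter kept 139 of the 141). Calls were lost by 31 genes without some array and by 28 under another setting, and 0 named genes and 0 lists reversed. Same-numbered arrays are not known to share more than a number. The correlation of their deviations was 0.0446, but with 2 arrays per group this is 1 comparison and cannot exclude a shared batch. With the replicate as a block 3073 genes passed, 2917 of them among the 3022. Neither filter on detection p was run, for want of a detection p. Signal over background limits dim genes: 40.6% to 40.9% of probes lay above 100 units.

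Of the gene lists, leaving out 1 array moved the adjusted p of NF-kB targets over 0.000803 to 0.0568 (highest without TAK1 KO replicate 2), of interferon-induced genes over 0.0305 to 0.821 (lowest without TAK1 KO replicate 2), of p53 targets over 0.0396 to 0.296 (lowest without TAK1 KO replicate 1) and of pancreatic acinar genes over 0.0241 to 0.169 (lowest without TAK1 KO replicate 2). Among genes above 100 units, lysosomal genes (0.0671), NF-kB targets (0.151) and neutrophil markers (0.0508) missed the threshold. With an estimated correlation 0 lists passed: the adjusted p was 0.288 for fetal liver, female-biased, bile duct and macrophage genes, 0.332 for extracellular matrix, 0.340 for drug metabolism, 0.349 for the cell cycle, 0.354 for fatty acid oxidation, lysosome, lipogenesis, bile acid, hepatocyte, NF-kB, NRF2, lymphocyte and neutrophil genes, 0.365 for autophagy and male-biased genes and 0.382 for cholesterol synthesis. With fry the adjusted p was 0.124 for fatty acid oxidation, 0.0829 for autophagy, 0.107 for lipogenesis, 0.112 for cholesterol synthesis and for neutrophil markers, 0.0586 for hepatocyte proteins, 0.0557 for NF-kB targets, 0.0505 for NRF2 targets and 0.131 for male-biased genes, whereas immediate-early genes passed (0.0258). With an estimated correlation camera has only the 2 residual degrees of freedom, so the misses there do not count against the lists. The cause of the other changes was not tested, apart from the fewer genes left by the filter.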

Other observations

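The gene families, the sex-chromosome values, the test of macrophage subsets, that of all sex-biased genes and that of clock gene spread were chosen after the results were seen, and the criteria by which the macrophage, clock and feeding tests were read were adjusted after their values were known. Of 31 measured genes with symbols starting in Rps, mostly ribosomal proteins, 12 rose in TAK1 KO liver and 0 fell (median log2 0.28), and of 37 starting in Rpl 14 rose and 1 fell (median 0.25), both with adjusted p = 0.977 with an estimated correlation. Rps10 was 1.66-fold and Rpl12 1.62-fold higher, whereas Rpl22 fell by 0.90 on the log2 scale. The symbols also cover ribosomal S6 kinases, of which Rps6kl1 is among the 12, and ribosomal protein genes have many near-identical pseudogenes. The beta tubulins Tubb6, Tubb2b, Tubb5 and Tubb4b, subunits of microtubules, rose 4.10-fold, 2.60-fold, 2.41-fold and 2.31-fold, 4 of 8 measured. Downward moved 5 of 14 Pex genes, which build peroxisomes (Pex16, Pex7, Pex11g, Pex2 and Pex3, with Pex16 at log2 -0.85 ± 0.09 SE), and 4 of 10 Ndufb genes of respiratory complex I, with Ndufb9 at -0.63 ± 0.09. Among 276 symbol families of at least 8 genes 16 passed camera, these with adjusted p-values of 0.000262 (Rps), 0.000474 (Rpl), 0.0228 (Tubb) and 0.0134 (Pex and Ndufb), and all with adjusted p = 0.977 with an estimated correlation. With 2 residual degrees of freedom the estimated correlation could hardly let any family pass. The medians of these 5 families kept their sign under each of the 7 scalings.

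Markers of several other cell types rose in TAK1 KO liver, and a lower share of hepatocytes would raise all of these alike. The median of endothelial markers lay below that of macrophage markers (difference -0.97, 95% bootstrap interval over genes -1.26 to -0.67, 18 and 21 genes above 100 units on any array). That floor admits macrophage genes dim in WT, such as Gpnmb and Trem2, only because they rose. With the WT mean above 100 units the difference was -0.95 (-1.27 to -0.67, 17 and 18 genes). With no floor it was -0.73 (-1.08 to -0.30). Single genes overlapped: all measured endothelial markers ran from log2 -0.68 to 0.34 and macrophage markers from -0.20 to 4.96. For these lists, the medians argue against a lower hepatocyte share as the whole cause. A change within the macrophages may add to a change in their number: genes of resident Kupffer cells had a median of 0.17 and genes of recruited or lipid-laden macrophages 2.30, a difference of -2.13 with an interval of -4.34 to 0.05 over 8 and 7 genes. An interval including 0 had been set as evidence against such a change, but this one is too wide to show its absence. Cd5l, Itgax and Ccr2 were below 100 units in both groups. They could not show a fall but could have shown a rise, and did not pass (adjusted p = 0.662, 0.165 and 0.766). Without them (mean of the 4 arrays above 100 units) the difference was -2.84 (-4.71 to -1.53, 7 and 5 genes). This stays open, because the genes were listed after the largest rises had been seen and Gpnmb, Mmp12 and Trem2, dim in WT, pass such a floor only by having risen. Clec7a rose 8.52-fold and Marco 2.61-fold, while Cd163, a scavenger receptor of resident macrophages, was 3.95-fold lower.

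Of 32 sex-biased genes 14 fell and 3 rose. Dilution of hepatocyte RNA would move sex-biased genes as far as hepatocyte proteins, but among genes above 100 units the median of 21 sex-biased genes, called or not, was -1.06 against -0.29 for 25 hepatocyte proteins (difference -0.77, 95% bootstrap interval -1.26 to -0.27), which argues against it as the whole cause for these genes; with the dim genes, which cannot show a fall, the difference was -0.00387 (-0.82 to 0.31). Arrays of different sex are argued against by Uty and the brighter Xist probe, whose highest value was at most 1.48 times the lowest. The other Xist probe read 313.8 to 503.5 units. This evenness does not bear on whether all 4 samples share a sex other than the labelled male. Both Xist probes lay at percentile 80.8 or above on each array, which argues against that label. The low Eif2s3y and Kdm5d values cannot decide it, since a low probe cannot tell an absent transcript from a poor probe. Uty read 112.4 to 142.2 units, and the sex of the samples stays open. Lower growth hormone signalling in hepatocytes is a hypothesis that the values allow in part, with a median of -0.60 over 6 responsive genes. Ghr, Igfals, Igfbp3 and Igf1 fell (log2 -1.36, -0.95, -0.70 and -0.50). Against it, Cish rose by 0.65 and Socs2 did not pass (-0.16, adjusted p = 0.628). Hepatocyte proteins fell as well, so the test may not be specific to the hormone.

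Some genes known to follow feeding or the time of day were lower in TAK1 KO liver: Depp1, Igfbp1 (log2 -2.15 ± 0.27 SE), Rgs16, Thrsp and Upp2 (-2.18 ± 0.44). Without WT replicate 2 the change of Thrsp was log2 -1.92 and its call was lost. These genes were named after their falls were seen, and Depp1, Rgs16 and Thrsp came from the largest falls. They therefore do not show how such genes moved as a set. Which way feeding or the hour would move each of them was not tested. A different hour of collection might lower such genes and stays open. The mean absolute change of 19 clock genes between the groups was 0.31, at percentile 55.3 of random lists matched on expression, and Nr1d1, Cry2 and Nfil3 fell (adjusted p = 0.00249, 0.0334 and 0.0277), but their mean SD within groups was 0.44 against a median of 0.11 in such lists, with Dbp, Ciart, Usp2, Tef, Arntl and Per2 varying 6.20-fold, 4.61-fold, 3.59-fold, 2.97-fold, 2.87-fold and 2.82-fold over the arrays. A percentile below the 95th had been set as evidence against the hour, and with group means this uncertain it cannot show that. A different feeding state stays open too, since the medians of fasting-induced and feeding-induced genes (-0.24 and -0.71, 8 genes each) differed by 0.46 with a 95% bootstrap interval of -0.10 to 0.89, too wide to show either a difference or its absence, although an interval including 0 had been set as evidence against it.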
